A study of Homo sapiens with 16 samples.

How the data were processed

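The submitters' processing notes name RMA, which subtracts background, normalizes arrays by quantiles and summarizes probes into log2 intensities. Its version is not stated, and a genome build is not given in the sources used here, so no coordinates are reported. RNA was extracted with Trizol and labelled with biotin. The table holds part of the array design, and how its entries were chosen is not stated. Knockdown arrays named in the series text were not analysed here.

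Of 23083 entries, 20841 carried 1 gene symbol, 1482 several and 760 none. Symbols were brought up to date through Entrez identifiers, of which 20808 matched, and 67 symbols changed. A gene with several entries was represented by the brightest, which left 20223 genes. A gene was tested when at least 4 of the 16 arrays exceeded the array's own 40th percentile, which left 12514. No further normalization was applied, and the largest difference between the medians of any pair of arrays was 0.134. FKBP5 and PGM3 had no entry with a single symbol that passed these steps and were not tested.

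Differences were tested with limma 3.58.1 in R 4.3.3: a model of group means over all 16 arrays (12 residual degrees of freedom), moderated by eBayes, two-sided, with Benjamini-Hochberg adjustment over the genes tested in each comparison and a threshold of 0.05. The interaction is the combination minus MDV3100 minus UDP-GlcNAc plus PBS. The median residual SD of a gene was 0.123. Replicate number was not used as a pairing, since the labels do not say what arrays of the same number share. The 24 same-numbered pairs of arrays had residual correlations between -0.115 and 0.0798 (median 0.00256). For 5 of the 16 arrays, the mean residual correlation with arrays of other groups was highest for their own number. The labels give no batch.

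Before the data were examined, 28 gene lists were fixed: hexosamine pathway and O-GlcNAc cycling, glycosyltransferases using UDP-sugars, pyrimidine synthesis and salvage, androgen-induced genes, androgen-repressed genes, mitosis, DNA replication, p53 targets and arrest, unfolded protein response, amino acid response (ATF4), cholesterol synthesis, fatty acid synthesis, glycolysis and glucose uptake, glucose-responsive genes (ChREBP, MondoA), hypoxia, FOXO targets and PI3K feedback, interferon-stimulated genes, NF-kB and inflammatory genes, immediate-early genes, autophagy and lysosome, oxidative stress (NRF2), metallothioneins and zinc, and neuroendocrine, luminal prostate, basal epithelial, fibroblast and mesenchymal, leukocyte and endothelial markers. The glycosyltransferase list, as fixed, also holds the sialyltransferase genes ST6GAL1, ST3GAL1 and ST6GALNAC1, whose donor is CMP-sialic acid and not a UDP-sugar. The 24 lists with at least 5 tested members were tested against the other genes with limma's camera at its preset inter-gene correlation of 0.01, adjusted over 144 list tests. Of the 39 calls, 5 held with an estimated correlation: androgen-induced genes in the 3 comparisons of MDV3100 or the combination against PBS or UDP-GlcNAc, and cholesterol synthesis for UDP-GlcNAc against PBS and for the combination against MDV3100. Counts per list are given over all genes tested and, where stated, adjusted over the list alone.

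Named genes followed a rule written before the data were examined. They are the 10 largest rises and 10 largest falls against PBS, and 5 and 5 in the other comparisons, among genes past the threshold whose 4 arrays of 1 group all lay above the 4 of the other (for the interaction without this last condition). Unnamed loci, small RNAs, ribosomal pseudogenes and sex-linked markers of identity were passed over. Up to 4 members of each list with the largest differences and fixed genes, including KLK3, KLK2, TMPRSS2, FKBP5, GFPT1, GNPNAT1, PGM3, UAP1, OGT, OGA, MKI67, CCND1, MYC and TXNIP, were added. Further members named where a list held few calls, among them KLK4, BUB1, POLA1, NEU1 and CMPK1, were chosen after their values were seen, and their dependence on the processing was not examined. A difference from a group whose mean lies under the 40th percentile of its arrays may be limited by background and so be a lower bound in size. Whether that percentile marks background was not tested. PNLIPRP3, with a PBS mean under it (arrays at 3.54 to 4.40), lay at 2.54 to 2.85 with MDV3100, so it is not a strict floor. Against PBS, such a group was present for 4 of the 20 genes named by size with UDP-GlcNAc. The counts were 7 of 20 with MDV3100 and 6 of 20 with the combination, also against PBS. They were 4 of 10 for the combination against MDV3100 and 2 of 10 against UDP-GlcNAc. In the interaction 5 of 10 had at least 1 such group, and the size would then have no bound. "Rose", "fell" and "changed" are used for values past the threshold.

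In a test of the method, 16 arrays were simulated from the PBS means and each gene's moderated residual SD. Known shifts were added to 200 genes and to the mitosis list. A log2 shift of 0.5 was found in 82.1% of the shifted genes for UDP-GlcNAc against PBS, 80.6% for MDV3100 against PBS, 73.1% for the combination against PBS and 49.3% for the interaction, and a shift of 1 in 98.5%, 97.0%, 98.5% and 92.5%. Between 7 and 14 of 12290 unshifted genes were called in each comparison. The shifted list was found each time, and 0 of the 23 other lists were called by camera. Noise was drawn independently for each gene, so false list calls from correlated members could not appear in this test.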

Results

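Gene expression was measured in C4-2 cells, a castration-resistant prostate cancer line derived from LNCaP, on 16 Affymetrix Human Gene ST 2.1 arrays. Cells were treated for 96 hours with phosphate-buffered saline (PBS), with 15 mM UDP-N-acetylglucosamine (UDP-GlcNAc), with 10 µM MDV3100 (enzalutamide, an antiandrogen) or with both agents, called the combination. Each of the 4 groups held 4 arrays. UDP-GlcNAc is the end product of the hexosamine pathway and the sugar donor for protein glycosylation. The table of log2 intensities held 23083 entries, of which 12514 genes were tested. Median log2 intensity per array lay between 5.39 and 5.52. The number of arrays limits the precision of each value, and the p-values measure only the spread between these samples, since the labels do not state whether replicates were separate cultures.

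Arrays grouped by treatment. Correlations across the genes tested lay between 0.989 and 0.994 for arrays of 1 group and between 0.960 and 0.992 for arrays of different groups. The first principal component held 57.7% of the variance and parted the arrays with MDV3100 (18.3 to 29.0) from those without it (-24.9 to -22.0). The second held 11.2% and parted MDV3100 alone (8.99 to 18.4) from the combination (-14.5 to -7.82) and PBS (4.81 to 6.18) from UDP-GlcNAc (-8.13 to -6.01).

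**Figure D1:**
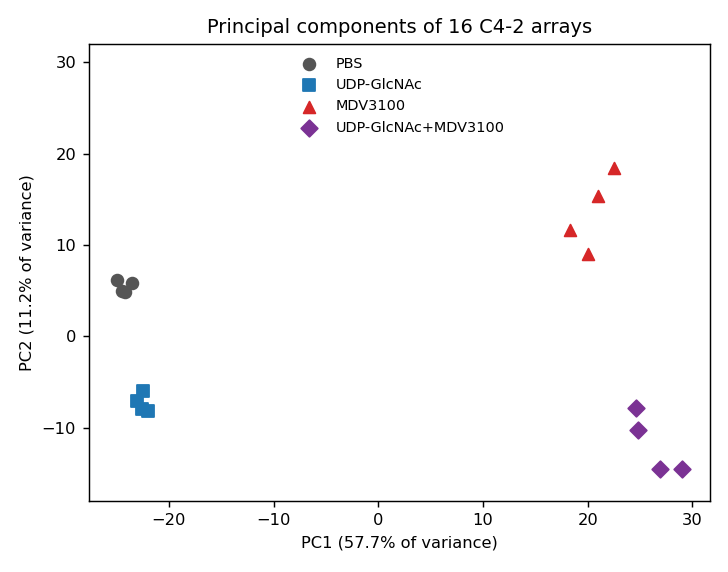
Scores of the 16 arrays on the first and second principal components (57.7% and 11.2% of the variance), coloured by treatment group. The 8 arrays with MDV3100 lie between 18.3 and 29.0 on the first component and the other 8 between -24.9 and -22.0.

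The first comparison asked what UDP-GlcNAc alone does to these cells. The largest rise was in STEAP4 (transcript cluster 17059567), an androgen-induced metalloreductase, whose log2 intensity went from 5.22 ± 0.10 to 7.17 ± 0.16 (SD, n = 4), a log2 difference of 1.95 (SE 0.10, adjusted p = 7.1e-08). HMOX1, a heme-degrading enzyme induced by oxidative stress, rose by 0.99 (SE 0.09, adjusted p = 7.9e-05), and CDKN2B, an inhibitor of cyclin-dependent kinases, rose by 0.78 (SE 0.13, adjusted p = 0.0044). TXNIP, which responds to glucose supply, fell by 0.58 (SE 0.11, adjusted p = 0.0067). The kallikreins KLK3 and KLK2, secreted products of androgen signalling, differed by 0.09 (SE 0.09, adjusted p = 0.64) and 0.14 (SE 0.08, adjusted p = 0.40), and TMPRSS2 by 0.08 (SE 0.05, adjusted p = 0.40). None of the 10 tested genes of the hexosamine pathway and O-GlcNAc cycling passed. The log2 difference was -0.10 in GNPNAT1, the acetyltransferase of that pathway, 0.09 in GFPT1, its first enzyme, 0.07 in UAP1, which makes UDP-GlcNAc, 0.13 in OGT and 0.10 in OGA.

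With UDP-GlcNAc, 559 genes changed against PBS, 296 of them up and 263 down, and 2427 had an unadjusted p under 0.05. A change of at least 1.5-fold was seen in 85 genes (53 up, 32 down), and 17 changed at least 2-fold. Of all genes tested, 15.02% had arrays that did not overlap between the groups, where chance gives 2.86%. The count was 312 to 421 without single arrays. It moved by more than 1.5-fold without PBS replicate 2 (371), PBS replicate 3 (360) and UDP-GlcNAc replicates 1 (312), 2 (348), 3 (348) and 4 (319). Array weights gave 842 genes, no filter on low values 294, and testing every table entry 323. Centring each array on its median gave 584 genes, 376 up and 208 down, so that 64.4% rose where 52.95% had risen. Fewer rose than fell when only the groups compared were fitted (268 up, 283 down) and without PBS replicate 4 (206 up, 215 down). Under the other alternatives run more rose than fell. After STEAP4, the largest rises were in HAR1B (1.55), RDH12 (1.41), SLC45A2 (1.13), ATOH1 (1.12), CD177 (1.11), ANGPT2 (1.09), ANKRD1 (1.09), SPRY4 (1.08) and PNLIPRP3 (1.06). The largest falls were in the anion exchanger SLC26A3 (-1.54), ASB11 (-1.37), CYP4F8 (-1.20), CYP4F22 (-1.15), FAM151A (-1.04), PRTFDC1 (-1.0002), CRISP3 (-0.90), SLC5A1 (-0.83), TOX3 (-0.82) and PPP1R14C (-0.81). CD177 lost its call when only the groups compared were fitted (adjusted p = 0.068). PPP1R14C lost it without 6 of the 8 arrays, 1 at a time (adjusted p = 0.053 to 0.12), and under 2 other settings (up to 0.078).

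Cholesterol synthesis genes rose with UDP-GlcNAc. Of 16 tested, 6 rose and 0 fell, 10 rose adjusted over the list alone, and the list median was 0.22 (adjusted p = 3.0e-08, and 0.028 with an estimated correlation). STARD4 rose by 0.62, HMGCS1 by 0.45 and LSS by 0.34. Of 12 oxidative stress genes, all were higher, 4 rose (HMOX1, SLC7A11 at 0.40, TXNRD1 at 0.29 and OSGIN1 at 0.25) and 7 rose adjusted over the list alone. Their median was 0.19 (adjusted p = 2.0e-07, and adjusted p = 0.090 with an estimated correlation). Of 27 androgen-induced genes, 5 rose (STEAP4, HPGD at 0.72, HERC3 at 0.39, ABCC4 at 0.24 and KLK4 at 0.24) and 0 fell, and adjusted over the list alone 9 rose and 2 fell. Their median was 0.14 (adjusted p = 2.2e-05, and adjusted p = 0.062 with an estimated correlation).

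Cell-cycle lists were lower with UDP-GlcNAc, with few members past the threshold. All 24 mitosis genes were lower, with a median of -0.24 (adjusted p = 1.5e-07, and adjusted p = 0.39 with an estimated correlation). AURKA fell (-0.36), and 2 genes fell adjusted over the list alone. All 22 DNA replication genes were lower, with a median of -0.25 (adjusted p = 5.6e-09, and adjusted p = 0.24 with an estimated correlation). CDT1 fell (-0.33), and 11 fell adjusted over the list alone. MKI67, the proliferation marker, differed by -0.21 (SE 0.13, adjusted p = 0.40), MYC by -0.19 (adjusted p = 0.11) and CCND1 by -0.11. AURKA lost its call without each of the 8 arrays in turn (adjusted p = 0.063 to 0.13), without a filter (0.10) and under both other scalings.

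The other lists did not pass with UDP-GlcNAc. The hexosamine list had a median of 0.12 (adjusted p = 0.067), 0 of 10 genes past the threshold and 0 adjusted over the list alone. Its call was gained with ranks (adjusted p = 0.040) and with replicate number as a block (0.046), where the estimated correlation gave 0.39. The pyrimidine list had a median of -0.10 (adjusted p = 0.052), and 1 of its 13 genes fell (DTYMK, -0.20). Of 24 glycosyltransferases, the sialyltransferase genes ST6GALNAC1 (0.55) and ST3GAL1 (0.26), whose products do not use UDP-sugars, rose and GALNT2 (-0.29) fell. Among 15 genes of the p53 and arrest list, CDKN2B, GADD45A (0.43) and GDF15 (0.29) rose and SESN1 (-0.34) fell. Single calls upward were DNAJB9 (0.28) in the unfolded protein response, SLC7A11 in the amino acid response, TNFAIP3 (0.50) in the NF-kB list, SLC30A1 (0.29) in the zinc list and LAMB3 (0.44) among 3 basal markers. Downward they were TXNIP among 7 glucose-responsive genes, SESN3 (-0.30) in the FOXO list and CD68 (-0.35) among 4 leukocyte markers. ELOVL5 (0.21) and ME1 (0.24) rose and THRSP (-0.50) fell among 13 fatty acid genes, HK2 (-0.27), PDK1 (-0.23) and PFKL (-0.17) fell among 19 glycolysis genes, and AGR2 (0.68) and KRT8 (0.56) rose among 12 luminal markers. No gene passed in the hypoxia, interferon, immediate-early, autophagy, neuroendocrine, fibroblast or androgen-repressed lists. The fatty acid, glucose-responsive, hypoxia and interferon lists had a mean, median and test that differed in sign. DTYMK, GALNT2, GDF15, THRSP, ELOVL5, HK2, PDK1, SESN3, TNFAIP3 and KRT8 each lost the call without 4 to 7 of the 8 arrays, 1 at a time (adjusted p = 0.050 to 0.13), and under 1 to 5 other settings (up to 0.11), and ST3GAL1 when only the groups compared were fitted (0.055).

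The second comparison measured the response to the antiandrogen alone. Androgen-induced genes fell: SLC45A3 (prostein, transcript cluster 16698521) went from 10.08 ± 0.11 to 5.54 ± 0.14 (SD, n = 4), a difference of -4.55 (SE 0.09, adjusted p = 1.1e-14). TMPRSS2, an androgen-driven serine protease, fell by 1.82 (SE 0.05, adjusted p = 6.6e-13), KLK2 by 1.89 (SE 0.08, adjusted p = 1.0e-10) and KLK3, which encodes prostate-specific antigen, by 1.11 (SE 0.09, adjusted p = 9.4e-08). CAMK2N1, an androgen-repressed inhibitor of CaM kinase II, rose by 4.08 (SE 0.12, adjusted p = 3.0e-12). In the hexosamine pathway, UAP1 fell by 1.15 (SE 0.06, adjusted p = 7.8e-10), GNPNAT1 (transcript cluster 16793052) by 0.52 (SE 0.06, adjusted p = 6.4e-06) and GFPT1 by 0.20 (SE 0.05, adjusted p = 0.0030). OGA, which removes O-GlcNAc from proteins, rose by 0.33 (SE 0.05, adjusted p = 0.00014), and OGT, which adds it, differed by 0.06 (adjusted p = 0.48). MKI67 differed by -0.04 (SE 0.13, adjusted p = 0.82), MYC by -0.04 (adjusted p = 0.69) and CCND1 by 0.05 (adjusted p = 0.41).

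MDV3100 changed 4858 genes against PBS, 2523 up and 2335 down. At least 1.5-fold changes were found in 1202 genes (707 up, 495 down) and at least 2-fold in 396. Of all genes tested, 34.7% had arrays that did not overlap between the groups, where chance gives 2.86%. The count stayed within 1.5-fold under each alternative run. Large rises were also seen in KCNJ13 (2.76), UPK1A (2.70), DAPK1 (2.61), KRT75 (2.60), MYOZ1 (2.59), CYP1A2 (2.53), PLPPR1 (2.52), DLX3 (2.50) and LRRN1 (2.41). The largest falls were in PIP (-4.88), CHRNA2 (-4.73), ELOVL2 (-4.71), SLC45A3, ST6GALNAC1 (-4.02), PGC (-3.78), SLC26A3 (-3.73), ZNF812P (-3.45), NPPC (-3.42) and CYP4F8 (-3.34).

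Of 27 androgen-induced genes, 26 fell with MDV3100 and 0 rose (26 fell and 1 rose adjusted over the list alone), with a median of -1.37 (adjusted p = 1.8e-26, and 0.00018 with an estimated correlation). The 3 tested androgen-repressed genes, CAMK2N1, CCN3 (1.06) and MET (0.78), all rose. MET lost its call without MDV3100 replicates 1 and 4 (adjusted p = 0.14). Unfolded protein response genes were lower in 17 of 17 cases, and 14 fell, among them DERL3 (-0.67), SDF2L1 (-0.63) and MANF (-0.57). Their median was -0.34 (adjusted p = 3.1e-06, and adjusted p = 0.067 with an estimated correlation). Of 13 fatty acid genes, 7 fell (ELOVL7 by 1.59, ELOVL5 by 1.06) and ACACB (0.72) and ELOVL6 (0.52) rose, with a median of -0.17 (adjusted p = 0.011, and adjusted p = 0.076 with an estimated correlation). Of 16 cholesterol genes, 8 fell (FDPS by 0.73, HMGCS1 by 0.53) and MSMO1 (0.28) and SC5D (0.25) rose, with a median of -0.20 (adjusted p = 0.035, and adjusted p = 0.26 with an estimated correlation). That call was lost without PBS replicate 3 (adjusted p = 0.064) and without MDV3100 replicates 2 and 3 (0.068).

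Glucose-responsive genes rose with MDV3100. Of 7, 5 rose, TXNIP by 1.14 (SE 0.11, adjusted p = 6.8e-07), MLXIPL by 0.63, ARRDC4 by 0.61, KLF10 by 0.46 and ARRDC3 by 0.27, with a median of 0.46 (adjusted p = 0.0037, and adjusted p = 0.067 with an estimated correlation). Of 5 neuroendocrine genes, SYT4 (1.39), ENO2 (1.08) and DDC (0.50) rose, with a median of 0.50 (adjusted p = 0.027, and adjusted p = 0.17 with an estimated correlation). That call was lost with ranks (0.065), without a filter (0.057) and without MDV3100 replicates 2 and 3 (0.099). The mitosis list was lower, with a median of -0.22 (adjusted p = 0.037, and adjusted p = 0.69 with an estimated correlation). KIF2C (-0.52), TTK (-0.35), KIF20A (-0.32), AURKA (-0.27) and BUB1 (-0.24) fell, and 2 genes fell adjusted over the list alone. The list call was lost without PBS replicate 3 (adjusted p = 0.061), MDV3100 replicate 1 (0.097) or MDV3100 replicate 3 (0.060), without MDV3100 replicates 2 and 3 (0.053) or 1 and 4 (0.11), after quantile normalization (0.062) and with fry (0.16). Of the genes, KIF20A lost its call without 7 of the 8 arrays, 1 at a time (0.051 to 0.089), and under 4 other settings (up to 0.15), and KIF2C (0.096) and TTK (0.065) without MDV3100 replicates 2 and 3. The DNA replication list had a median of -0.13 (adjusted p = 0.21), with MCM6 (0.18) up, FEN1 (-0.38), CDC45 (-0.37), TK1 (-0.31) and POLA1 (-0.21) down, and 0 past the threshold adjusted over the list alone. FEN1, CDC45 and TK1 lost their calls without 3 to 8 of the 8 arrays, 1 at a time (0.050 to 0.14), and under 1 to 5 other settings (up to 0.28).

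Other lists held calls in both directions with MDV3100 and did not pass. Of all 12514 genes tested, 4858 changed with MDV3100. Calls of single members, here and in the next paragraphs, therefore do not by themselves mark a response of a list. In the hexosamine list 4 of 10 genes rose (GNPDA1 0.38, OGA, UAP1L1 0.32 and GNPDA2 0.21) and UAP1, GNPNAT1 and GFPT1 fell, with a median of 0.07, a negative mean and adjusted p = 0.94. GNPDA1 lost its call without MDV3100 replicates 1 and 4 (0.20). Of 24 glycosyltransferases 5 rose (GALNT3 0.99, MGAT4A 0.49, ST3GAL1 0.35, EXT1 0.34 and C1GALT1 0.29) and 7 fell, with the sialyltransferase gene ST6GALNAC1 at -4.02 (list adjusted p = 0.42). Of 13 pyrimidine genes UPP1 (0.51) and CMPK1 (0.15) rose and DHODH (-0.71), TYMS (-0.51), CTPS1 (-0.35), DTYMK (-0.32) and UCKL1 (-0.15) fell (list adjusted p = 0.14). UPP1 lost its call without MDV3100 replicates 1 and 4 (0.080).

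Among p53 targets CDKN1A (0.80), TP53INP1 (0.75), SESN1 (0.42), RRM2B (0.38) and MDM2 (0.15) rose with MDV3100 and GADD45A (-0.66) and TNFRSF10B (-0.61) fell. In the FOXO list 6 rose, with SESN3 at 0.96 and PIK3IP1 at 0.84, and IGF1R (-1.88), KLF6 (-0.89), IRS2 (-0.50) and CITED2 (-0.37) fell. In the hypoxia list INSIG2 (0.62), MXI1 (0.41), VEGFA (0.30) and BNIP3L (0.19) rose and NDRG1 (-1.46), ANKRD37 (-0.90) and ANGPTL4 (-0.58) fell. Luminal markers GATA2 (0.93), ACP3 (0.54), CDH1 (0.36) and HOXB13 (0.19) rose, and SPDEF (-1.67), KRT19 (-1.41), AGR2 (-0.72), FOXA1 (-0.41) and KRT18 (-0.30) fell. Of the autophagy genes 6 rose and 1 fell (WIPI1, -0.50). Oxidative stress genes HMOX1 (1.19), FTL (0.39), GCLC (0.37) and NQO1 (0.14) rose and GSR (-0.26), TXNRD1 (-0.21) and OSGIN1 (-0.18) fell. Glycolysis genes ENO2 (1.08), ALDOC (0.35) and PFKL (0.15) rose and HK2 (-0.62), SLC2A1 (-0.60), HK1 (-0.35), LDHA (-0.32) and PGK1 (-0.18) fell. Interferon genes IFIT3 (0.64), IFIT5 (0.62), RIGI (0.46) and IFI6 (0.45) rose and HERC5 (-0.48), USP18 (-0.36) and HERC6 (-0.34) fell.

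Smaller sets of calls with MDV3100 lay in the remaining lists. SLC7A5 (0.18) and NUPR1 (0.13) rose and ATF3 (-1.05) and TRIB3 (-0.32) fell in the amino acid list. LCN2 (0.42) rose and TNFAIP3 (-0.96), NFKBIA (-0.84) and NFKB2 (-0.31) fell in the NF-kB list. IER3 (0.40), IER2 (0.34) and JUNB (0.28) rose and ATF3, NR4A1 (-0.69) and KLF4 (-0.35) fell among immediate-early genes. MT1F (0.70) and SLC30A1 (0.29) rose and SLC39A10 (-0.60) fell in the zinc list, and VIM (0.21) rose and SNAI2 (-3.27) and SPARC (-0.79) fell among fibroblast markers. The adjusted p of the lists not past the threshold lay between 0.067 and 0.99, and the hexosamine, amino acid, hypoxia and FOXO lists had a mean, median and test that differed in sign. IFIT3, SLC7A5, TRIB3, LCN2 and VIM lost their calls without 3 to 6 of the 8 arrays, 1 at a time (adjusted p = 0.053 to 0.14), and under 1 to 8 other settings (up to 0.48). IER3 lost its call with the mean of its entries (adjusted p = 0.60), KLF4 without MDV3100 replicates 2 and 3 (0.067) and ANGPTL4 without these or replicates 1 and 4 (0.058). The basal list had ITGB4 (1.34) up, and the leukocyte list LYZ (-0.72) and CD68 (-0.19) down. CD68 lost its call without 6 of the 8 arrays, 1 at a time (0.056 to 0.13), and under 5 other settings (up to 0.40). No endothelial marker passed the filter on low values.

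The third comparison set the combination against PBS. MKI67 (transcript cluster 16719515) went from 9.38 ± 0.17 to 8.03 ± 0.33 (SD, n = 4), a difference of -1.35 (SE 0.13, adjusted p = 5.4e-07), and MYC, a growth-promoting transcription factor, fell by 0.36 (SE 0.06, adjusted p = 0.00030). SLC45A3 fell by 4.37 (SE 0.09, adjusted p = 2.0e-14) and KLK3 by 1.35 (SE 0.09, adjusted p = 8.1e-09). KLK2 fell by 1.95 and TMPRSS2 by 1.60. GNPNAT1 fell by 0.73 (SE 0.06, adjusted p = 1.1e-07) and UAP1 by 1.04, while OGA rose by 0.41 and TXNIP by 0.81. CYP1A2, a target of the aryl hydrocarbon receptor, rose by 3.66 (SE 0.16, adjusted p = 1.4e-10). CCND1 differed by 0.04 (adjusted p = 0.55).

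The combination changed 5903 genes against PBS, 3016 up and 2887 down, of which 1803 changed at least 1.5-fold (963 up, 840 down) and 610 at least 2-fold. Of all genes tested, 44.4% had arrays that did not overlap between the groups, where chance gives 2.86%. The count stayed within 1.5-fold under each alternative run. The largest rises were in CAMK2N1 (3.95), KCNJ13 (3.70), CYP1A2, MYOZ1 (3.08), DLX3 (3.07), CFAP107 (2.98), KRT75 (2.93), HTRA1 (2.65), HAR1B (2.58) and SLFN5 (2.45). The largest falls were in PIP (-5.01), ELOVL2 (-4.97), CHRNA2 (-4.41), SLC45A3, NPPC (-3.79), SLC26A3 (-3.50), ST6GALNAC1 (-3.46), GNMT (-3.40), ZNF812P (-3.21) and IGF1 (-3.18).

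All 24 mitosis genes fell with the combination, ASPM by 1.58 and KIF2C by 1.53, with a median of -1.21 (adjusted p = 9.5e-16, and adjusted p = 0.21 with an estimated correlation). All 22 DNA replication genes fell, CDC45 by 1.58 and GINS2 by 1.37, with a median of -0.91 (adjusted p = 2.6e-12, and adjusted p = 0.17 with an estimated correlation). Of 27 androgen-induced genes 23 fell and 1 rose (MED28, 0.14), with a median of -1.35 (adjusted p = 9.6e-18, and 0.00060 with an estimated correlation). Of 17 unfolded protein response genes 14 fell, SDF2L1 by 1.03, with a median of -0.29 (adjusted p = 8.0e-06, and adjusted p = 0.072 with an estimated correlation). Of 12 oxidative stress genes 10 rose, HMOX1 by 1.79 and GCLC by 0.79, and GSR fell (-0.19), with a median of 0.39 (adjusted p = 6.1e-04, and adjusted p = 0.24 with an estimated correlation). Of 15 autophagy and lysosome genes 11 rose, GABARAPL1 by 0.69 and LAMP1 by 0.48, and WIPI1 fell (-0.38), with a median of 0.30 (adjusted p = 0.0037, and adjusted p = 0.12 with an estimated correlation). Of 15 genes of the p53 and arrest list 8 rose, CDKN2B by 1.45 and CDKN1A by 1.28, and TNFRSF10B fell (-0.45). The list median was 0.32 (adjusted p = 0.014, and adjusted p = 0.34 with an estimated correlation). The counts adjusted over the list alone for these lists were within 1 gene of those given.

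Of 7 glucose-responsive genes 5 rose with the combination (ARRDC4 0.91, TXNIP, KLF10 0.53, MLXIPL 0.41 and ARRDC3 0.26) and 7 rose adjusted over the list alone, with a median of 0.41 (adjusted p = 0.010, and adjusted p = 0.076 with an estimated correlation). Of 13 pyrimidine genes 7 fell, TYMS by 1.62 and DHODH by 0.93, and UPP1 (1.25) and CMPK1 (0.17) rose, with a median of -0.32 (adjusted p = 0.043, and adjusted p = 0.17 with an estimated correlation). That call was lost with ranks (0.061), without a filter (0.073) and without combination replicate 4 (0.051). In the hexosamine list 5 of 10 genes rose (GNPDA1 0.58, OGA, UAP1L1 0.29, GNPDA2 0.25 and OGT 0.19) and UAP1 and GNPNAT1 fell, with a median of 0.20 (adjusted p = 0.62). OGT lost its call without PBS replicate 4 (0.059) or combination replicate 1 (0.064). The 3 androgen-repressed genes rose, and MET lost its call without combination replicate 4 (0.057). LAMB3 (1.25) and ITGB4 (1.05) rose among 3 basal markers, and 0 of 4 leukocyte markers passed. Since 5903 of all 12514 genes tested changed with the combination, calls of single members do not by themselves mark a response of a list. The remaining lists had an adjusted p between 0.13 and 0.94, among them cholesterol synthesis with a median of 0.09 (adjusted p = 0.58).

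**Figure D2:**
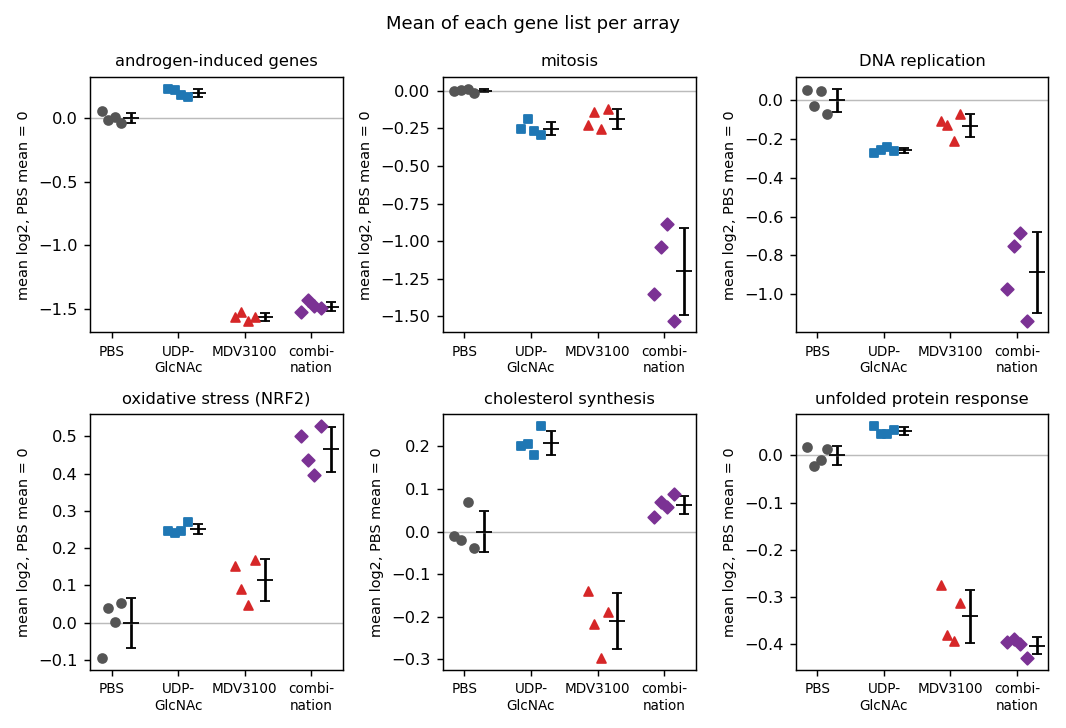
Mean log2 intensity of gene lists relative to the PBS mean, per array (points) with the group mean ± SD (bars, n = 4), by treatment. The mitosis list mean is -0.25 with UDP-GlcNAc, -0.19 with MDV3100 and -1.20 with the combination, and the androgen-induced mean is 0.20, -1.56 and -1.48.

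The fourth comparison, the combination against MDV3100 alone, asked what UDP-GlcNAc adds to the antiandrogen. Proliferation genes fell: MKI67 by 1.30 (SE 0.13, adjusted p = 8.7e-06), the mitotic kinesin gene KIF18B by 1.42 (SE 0.10, adjusted p = 1.2e-06), the replication factor TICRR by 1.40 (SE 0.13, adjusted p = 7.7e-06) and the linker histone gene H1-5 by 1.65 (SE 0.13, adjusted p = 2.4e-06). MYC fell by 0.32 (SE 0.06, adjusted p = 0.0033). CDKN2B went from 6.05 ± 0.08 to 7.58 ± 0.36 (SD, n = 4), a rise of 1.54 (SE 0.13, adjusted p = 3.7e-06). KLK3 differed by -0.24 (SE 0.09, adjusted p = 0.074), KLK2 by -0.06 (adjusted p = 0.67), STEAP4, under the 40th percentile in both groups, by -0.19 (SE 0.10, adjusted p = 0.24), UAP1 by 0.11 (adjusted p = 0.23) and CCND1 by -0.02 (adjusted p = 0.87). TMPRSS2 rose by 0.23 (SE 0.05, adjusted p = 0.0051), a call that was lost when only the groups compared were fitted (0.056). GNPNAT1 fell by 0.21, a call that was lost without MDV3100 replicates 1 (0.055) or 4 (0.071) or combination replicate 1 (0.077), without MDV3100 replicates 1 and 4 together (0.16), without a filter (0.066), with replicate number as a block (0.052) and when only the groups compared were fitted (0.12). GFPT1 rose by 0.14, a call that was lost without 6 of the 8 arrays, 1 at a time (0.068 to 0.13), and under 5 other settings (up to 0.30, without MDV3100 replicates 2 and 3).

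Against MDV3100 alone 1939 genes changed, 949 up and 990 down. More rose than fell after quantile normalization (1067 up, 970 down) and after centring on the median (1089 up, 936 down). The same held without MDV3100 replicate 1 (1041 up, 942 down) and without replicates 1 and 4 (1389 up, 1141 down). Without replicates 2 and 3, fewer rose than fell (408 up, 603 down). At least 1.5-fold changes numbered 373 (114 up, 259 down) and at least 2-fold changes 87. Of all genes tested, 19.4% had arrays that did not overlap between the groups, where chance gives 2.86%. When only the groups compared were fitted the count was 1178. The count was 1011 without MDV3100 replicates 2 and 3 (888 of them among the 1939) and 2530 without replicates 1 and 4. The other rises among the 5 largest were in PIRT (1.93), KLK7 (1.56), CYP1A1 (1.40) and the laminin gene LAMB3 (1.34), and the other falls in H2AC14 (-1.54) and E2F7 (-1.36). H2AC14 lost its call without MDV3100 replicates 2 and 3 (adjusted p = 0.050).

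All 24 mitosis genes fell against MDV3100, MKI67 by 1.30, ASPM by 1.27 and KIF11 by 1.22, with a median of -1.03 (adjusted p = 2.3e-31, and adjusted p = 0.076 with an estimated correlation). All 22 DNA replication genes fell, UHRF1 by 1.23 and CDC45 by 1.21, with a median of -0.71 (adjusted p = 6.9e-25, and adjusted p = 0.067 with an estimated correlation). Of 16 cholesterol genes 10 rose and 0 fell, STARD4 by 0.70 and LSS by 0.41, and 13 rose adjusted over the list alone, with a median of 0.28 (adjusted p = 1.9e-07, and 0.036 with an estimated correlation). All 12 oxidative stress genes were higher and 9 rose, HMOX1 by 0.61, TXNRD1 by 0.54 and GCLM by 0.53, with a median of 0.39 (adjusted p = 1.8e-08, and adjusted p = 0.076 with an estimated correlation). Of 15 genes of the p53 and arrest list 8 rose, CDKN1A by 0.48. The list median was 0.29 (adjusted p = 9.2e-05, and adjusted p = 0.17 with an estimated correlation). Of 15 autophagy genes 5 rose (GABARAPL1 0.51, ATP6V1H 0.32, SQSTM1 0.23, HEXA 0.21 and NEU1 0.17), with a median of 0.15 (adjusted p = 0.010, and adjusted p = 0.17 with an estimated correlation). SQSTM1 lost its call without combination replicate 1 (0.053) and under 2 other settings (up to 0.091), HEXA without 5 arrays, 1 at a time (0.050 to 0.083), and under 4 other settings (up to 0.12), ATP6V1H without MDV3100 replicates 2 and 3 (0.088), and the list without MDV3100 replicates 1 and 4 (0.066). In the hypoxia list INSIG2 (0.58), P4HA2 (0.55) and NDRG1 (0.23) rose, with a median of 0.14 (adjusted p = 0.023, and adjusted p = 0.17 with an estimated correlation). NDRG1 lost its call without 5 arrays, 1 at a time (0.079 to 0.11), and under 5 other settings (up to 0.24), and the list without combination replicate 4 (0.057) or MDV3100 replicates 2 and 3 (0.068).

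Androgen-induced genes went both ways against MDV3100: 8 of 27 rose, with TRPM8 at 0.92, HERC3 at 0.85 and ABCC4 at 0.69, and 5 fell (GNMT -0.51, EAF2 -0.36, C1orf116 -0.35, MPHOSPH9 -0.33 and SPDEF -0.28), with a median of 0.01 (adjusted p = 0.28). SPDEF lost its call when only the groups compared were fitted (adjusted p = 0.063) and without MDV3100 replicates 2 and 3 (0.12). The hexosamine list had a median of 0.09 (adjusted p = 0.27), with GFPT1 up and GNPNAT1 down. In the pyrimidine list TYMS (-1.11), CAD (-0.42), DTYMK (-0.34) and UCKL1 (-0.17) fell and UPP1 (0.74) rose (list adjusted p = 0.079), with CAD lost under the same settings (0.052 and 0.14). SYT4 (-0.63) and DDC (-0.47) fell among neuroendocrine markers and OAS3 (-0.84) and IFI6 (-0.35) among interferon genes. The lists that did not pass had an adjusted p between 0.067 and 0.99.

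The fifth comparison, the combination against UDP-GlcNAc alone, gave the antiandrogen response in the presence of the sugar nucleotide. STEAP4 fell by 4.01 (SE 0.10, adjusted p = 3.4e-13). This may be a lower bound, since its mean in the combination (3.16) lay under the 40th percentile of those arrays (4.43). SLC45A3 fell by 4.43 (SE 0.09, adjusted p = 1.6e-14) and MKI67 by 1.13 (SE 0.13, adjusted p = 4.0e-06). KLK3 fell by 1.44, KLK2 by 2.09 and TMPRSS2 by 1.68, and TXNIP rose by 1.38. The count was 5368 genes, 2811 up and 2557 down, with 1586 at least 1.5-fold (869 up, 717 down) and 489 at least 2-fold. It stayed within 1.5-fold under each alternative run. Of all genes tested, 43.3% had arrays that did not overlap between the groups, where chance gives 2.86%. The 5 largest rises were in KCNJ13 (3.61), CAMK2N1 (3.54), CYP1A2 (3.15), KRT75 (3.07) and the sodium-glucose transporter gene SLC5A1 (2.85), and the 5 largest falls in CHRNA2 (-4.84), ELOVL2 (-4.64), PIP (-4.58), SLC45A3 and ST6GALNAC1 (-4.01). Of these genes, KRT75 with UDP-GlcNAc and CHRNA2 with the combination had a mean under the 40th percentile.

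Against UDP-GlcNAc 26 of 27 androgen-induced genes fell and MED28 rose (0.17), with a median of -1.44 (adjusted p = 5.3e-24, and 0.00018 with an estimated correlation). All 24 mitosis genes fell, with a median of -0.97 (adjusted p = 2.7e-14, and adjusted p = 0.24 with an estimated correlation), and 20 of 22 DNA replication genes, with a median of -0.69 (adjusted p = 2.5e-09, and adjusted p = 0.24 with an estimated correlation). Of 17 unfolded protein response genes 14 fell, SDF2L1 by 1.21, with a median of -0.45 (adjusted p = 1.6e-07, and adjusted p = 0.055 with an estimated correlation). Of 7 glucose-responsive genes 4 rose (TXNIP, ARRDC4 1.07, KLF10 0.44 and MLXIPL 0.29), with a median of 0.31 (adjusted p = 0.013, and adjusted p = 0.076 with an estimated correlation). Of 15 autophagy genes 10 rose and WIPI1 fell (-0.51), with a median of 0.22 (adjusted p = 0.014, and adjusted p = 0.17 with an estimated correlation). The hexosamine list had UAP1 (-1.11), GNPNAT1 (-0.62) and GFPT1 (-0.14) down and GNPDA1 (0.33), GNPDA2 (0.33) and OGA (0.31) up, with a median of 0.06, a negative mean and adjusted p = 0.89. GFPT1 lost its call without UDP-GlcNAc replicate 1 (0.051) or combination replicate 2 (0.064) and under 2 other settings (up to 0.057), and GNPDA1 without UDP-GlcNAc replicates 1 (0.067) or 3 (0.053) or combination replicates 1 (0.089) or 2 (0.080). The remaining lists had an adjusted p between 0.061 and 0.94. Here too, 5368 of all 12514 genes tested changed, so calls of single members do not by themselves mark a response of a list.

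The interaction tested whether the combination differed from the sum of both agents' log2 effects. STEAP4, which rose with UDP-GlcNAc alone, stood at 3.35 ± 0.19 with MDV3100 and 3.16 ± 0.13 with the combination (SD, n = 4), an interaction of -2.13 (SE 0.14, adjusted p = 2.7e-06). Both means lay under the 40th percentile of those arrays (4.404 and 4.430), so a UDP-GlcNAc effect beside MDV3100 may not be detectable at this signal. The size of this interaction may therefore depend on a signal floor. ADRA2A, an adrenergic receptor gene, was at 5.45 with PBS, 6.38 with UDP-GlcNAc, 6.50 with MDV3100 and 5.58 with both, an interaction of -1.86 (SE 0.19, adjusted p = 0.00026). MKI67 had an interaction of -1.09 (SE 0.18, adjusted p = 0.0075) and H1-5 of -1.17 (SE 0.19, adjusted p = 0.0060). The interaction was positive in SLC26A3 at 1.77 (SE 0.23, adjusted p = 0.0015) and in CYP4F8 at 1.55 (SE 0.19, adjusted p = 0.0013), genes that had fallen with each agent. SLC26A3 also lay under that percentile in both arms with MDV3100. KLK3 had an interaction of -0.33 (SE 0.12, adjusted p = 0.22) and CDKN2B of 0.76 (SE 0.19, adjusted p = 0.050, not past the threshold).

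The interaction passed for 278 genes, 101 up and 177 down, with 1801 at an unadjusted p under 0.05. It reached 1.5-fold in 170 genes (55 up, 115 down) and 2-fold in 31. Of the 278 genes, 74 changed with UDP-GlcNAc alone, 231 changed with UDP-GlcNAc beside MDV3100 and 150 changed with MDV3100 alone. The UDP-GlcNAc effect had opposite signs in the absence and presence of MDV3100 for 126 genes, and 9 of these passed in both. The count was 182 without MDV3100 replicate 2, 169 without a filter and 185 with every table entry tested. It was 90 without MDV3100 replicates 2 and 3 (36 up, 54 down, 78 of them among the 278) and 608 without replicates 1 and 4 (322 up, 286 down). The share that rose was 36.3% with all arrays and 52.96% without replicates 1 and 4. PIRT (1.76), KLK7 (1.61), ASB11 (1.54), SLC45A2 (-1.63) and ATOH1 (-1.28) complete the 10 largest, and each lost its call without replicates 2 and 3 (adjusted p = 0.054 to 0.085). ASB11 lay under the 40th percentile in both arms with MDV3100, and PIRT and KLK7 in the 3 other groups than the combination.

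All 24 mitosis genes had a negative interaction and 18 passed (23 adjusted over the list alone), ASPM at -1.08 and PLK1 at -0.94, with a median of -0.79 (adjusted p = 6.1e-30, and adjusted p = 0.076 with an estimated correlation). All 22 DNA replication genes were negative and 6 passed (19 adjusted over the list alone), CDC45 at -0.97 and UHRF1 at -0.83, with a median of -0.48 (adjusted p = 2.1e-18, and adjusted p = 0.087 with an estimated correlation). Without MDV3100 replicates 2 and 3, PLK1 (0.054), CDC45 (0.052) and UHRF1 (0.065) lost their calls. The p53 and arrest list had a median of 0.25 (adjusted p = 0.0036, and adjusted p = 0.26 with an estimated correlation). Of its 15 genes 0 passed the threshold, and 2 passed adjusted over the list alone. The FOXO list had a median of 0.14 (adjusted p = 0.0066, and adjusted p = 0.067 with an estimated correlation), with SESN3 (0.47) past the threshold and 3 genes adjusted over the list alone, and it was lost without replicates 1 and 4 (0.066). The unfolded protein response list had a median of -0.11 (adjusted p = 0.019, and adjusted p = 0.26 with an estimated correlation), with SDF2L1 (-0.59) past the threshold. That list call was lost without MDV3100 replicate 1 (0.085) or 4 (0.054) and without both (0.35). SDF2L1 lost its call without each of 10 of the 16 arrays (0.053 to 0.071) and SESN3 without each of 5 (0.052 to 0.058), and under 4 and 2 other settings (up to 0.11). The androgen-induced list had a median of -0.08 (adjusted p = 0.28), with ABCC4 (0.45), HERC3 (0.46) and TRPM8 (0.78) up and STEAP4 and MPHOSPH9 (-0.52) down. The hexosamine list had 0 genes past the threshold (adjusted p = 0.86), and cholesterol synthesis also 0 (adjusted p = 0.36).

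**Figure D3:**
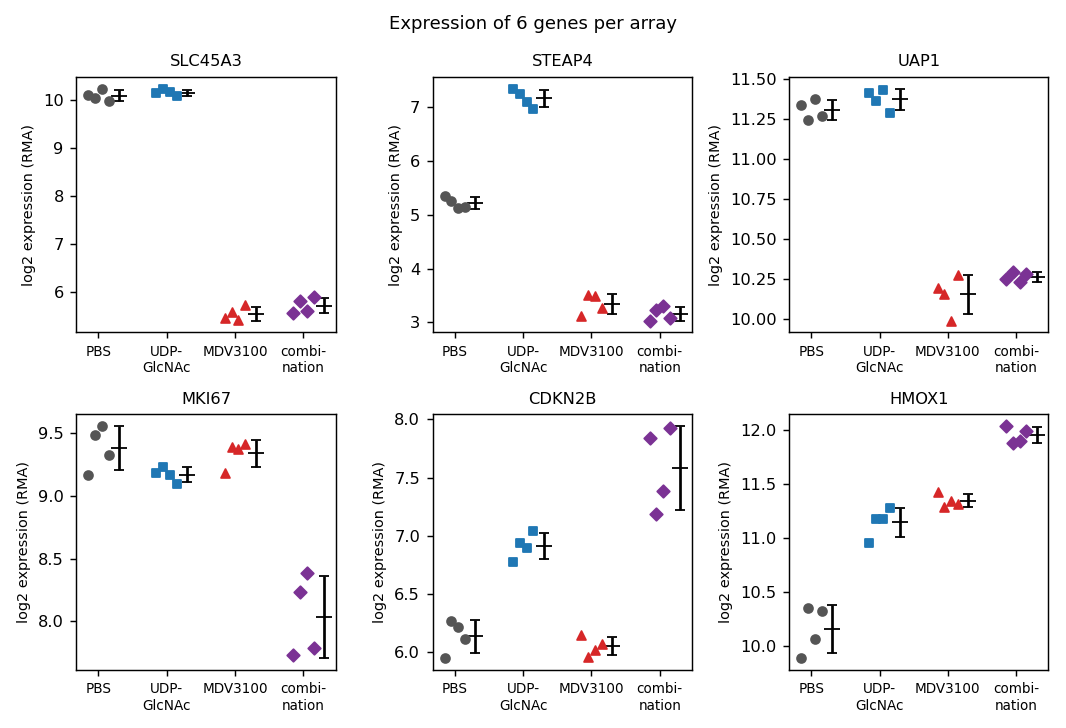
Log2 intensity of selected genes per array (points) with the group mean ± SD (bars, n = 4), by treatment. STEAP4 stands at 5.22 with PBS, 7.17 with UDP-GlcNAc, 3.35 with MDV3100 and 3.16 with the combination, and MKI67 at 9.38, 9.17, 9.34 and 8.03.

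Effects were then compared across genes, which are not independent replicates. UDP-GlcNAc and MDV3100, each against PBS, had a correlation of 0.156 across the genes tested, where unchanged groups sharing the PBS arrays gave 0.502 in simulation. The simulation holds no treatment effects, which widen the observed spread, so these correlations are not directly comparable. With separate pairs of PBS arrays as controls the mean correlation was 0.0559 (0.0441 to 0.0683 over 6 splits). The observed covariance was 0.0117 and the simulated one 0.00637. Both agents raised 135 genes and lowered 105, while 76 rose with UDP-GlcNAc and fell with MDV3100 and 55 did the reverse, counts to which the shared PBS arrays contribute. In a pair of comparisons chosen after the data were seen because they share no array, the UDP-GlcNAc effects without and with MDV3100 had a correlation of 0.428 (-0.000829 in simulation), the same sign in 484 of 559 genes (86.6%) and a median ratio of 0.615. The MDV3100 effects without and with UDP-GlcNAc had a correlation of 0.860, the same sign in 4660 of 4858 genes (95.9%) and a median ratio of 0.922. Both ratios set the effect with the other agent over the effect without it, for genes chosen by passing in the latter. That choice tends to inflate the latter effect, so a ratio under 1 does not by itself show a weaker response. No ratio was simulated.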

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

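Of the tests below, those of single arrays, of the linear scale, of the signal floor and of selection, and that of the androgen-induced list without STEAP4, were chosen after the result was seen.

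Cell-cycle genes were lower with the combination than the sum of both agents, by a mean interaction of -0.76 for the mitosis list and -0.50 for the DNA replication list (adjusted p = 0.076 and 0.087 with an estimated correlation). Intensity-dependent normalization was argued against by random lists of matched intensity, whose median interaction was 0.0099. Of these, 0 of 10000 had a median as low as that of both lists together (-0.68). A single array as the cause was argued against by the weakest mean without 1 array, -0.54 where all arrays gave -0.64. The log scale as the cause was argued against by effects added on the linear scale, where the combination stood at 0.644 of the expected level in the median and under it for 46 of 46 members. A joint effect of both agents on proliferation may therefore explain the pattern, a hypothesis found and tested on the same data that leaves the time spent in culture, cell loss and the single dose of each agent untested.

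Of the 74 genes changed by UDP-GlcNAc alone that had an interaction past the threshold, it was of the opposite sign for 53, whose change was smaller or opposite beside MDV3100, and of the same sign for 21, whose change was larger. The UDP-GlcNAc effect changed sign for 44 of the 53, and 9 passed the threshold in both settings. Choosing genes by the UDP-GlcNAc effect favours opposing interactions, since both share arrays, but 100 simulations with no interaction gave a mean of 5.62 opposing genes, at most 14, and a mean of 0.19 of the same sign, so both kinds exceeded them. A signal floor in the arms with MDV3100 was argued against as the common cause, since 13.2% of the 53 genes (7) lay under the 40th percentile in either arm, but it stays open for these 7, among them STEAP4, SLC26A3 and ASB11. For the others a dependence of the UDP-GlcNAc response on androgen signalling is a possible explanation, which the design names and no test here separates from other effects of MDV3100.

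Androgen-induced genes were higher with UDP-GlcNAc, by a mean of 0.198. STEAP4 alone was argued against as the cause, since the mean was 0.131 without it, over the 26 members left. Random lists of matched intensity had a median of 0.0014, and 0 of 10000 had a median as high as that of the list (0.136), against intensity-dependent normalization. A general rise in androgen signalling could not be told from a change limited to the list: over 6 splits of the PBS arrays, genes outside it that MDV3100 had lowered at least 2-fold had medians of -0.0380 to 0.0226 with members going both ways (SD 0.407 to 0.433), above 23.56% to 95.2% of random lists. The criterion set beforehand, a median within the middle 95% of random lists, was too weak to exclude a small rise with 2 PBS arrays on each side, so this explanation stays open, and the list call itself was lost with an estimated correlation (adjusted p = 0.062).

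The test of the interaction also passed for 278 genes in all. Among lists, the mean interaction was 0.21 for the p53 and arrest list, -0.11 for the unfolded protein response and 0.18 for the FOXO list. Each of these list calls was lost with an estimated correlation (adjusted p = 0.26, 0.26 and 0.067). The unfolded protein response and FOXO calls were also lost without MDV3100 replicates 1 and 4 (0.35 and 0.066). Among the 10 genes named, it was 1.77 for SLC26A3, 1.76 for PIRT, 1.61 for KLK7, 1.55 for CYP4F8, 1.54 for ASB11, -2.13 for STEAP4, -1.86 for ADRA2A, -1.63 for SLC45A2, -1.28 for ATOH1 and -1.17 for H1-5. The values of STEAP4, SLC26A3 and ASB11 rest on arms with MDV3100 under the 40th percentile, and those of PIRT and KLK7 on 3 such groups.

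Each gene count was set against the 35 splits of the 8 arrays of each pairwise comparison. The interaction count was set against 100 assignments of the residuals of an additive model to the arrays, the real one included. In each, 1, the real one, gave as many genes. The other splits mix arrays of both groups, so a real difference enters the spread and lowers their counts. A real interaction likewise stays in the reassigned residuals. Low counts in the others therefore do not by themselves exclude chance. The real count and the highest of the others were 559 and 3 for UDP-GlcNAc against PBS, 4858 and 1 for MDV3100 against PBS, and 5903 and 0 for the combination against PBS. They were 1939 and 1 for the combination against MDV3100, 5368 and 0 for the combination against UDP-GlcNAc, and 278 and 1 for the interaction.

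Single arrays stood apart from the other 3 of their group, by a gap over 0.829 of the group's range, in 4 of 112 groups for array measures and list means. Chance gives about 1 in 20. The interferon list mean, relative to PBS, was -0.0618 in UDP-GlcNAc replicate 1 (0.0529 to 0.0555 in the others) and 0.147 in combination replicate 3. The oxidative stress mean was 0.271 in UDP-GlcNAc replicate 4, and the metallothionein and zinc mean -0.0749 in PBS replicate 1. No explanation was tested.

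Among 66 named genes, 20 of 264 groups (7.58%) had an array apart in the same way, as log2 intensities. In PBS these were PNLIPRP3 in replicate 3 (3.54), CRISP3 in replicate 1 (8.26), KCNJ13 in replicate 4 (5.22), CYP1A2 in replicate 3 (6.62) and ADRA2A in replicate 1 (5.80). With UDP-GlcNAc they were RDH12 in replicate 4 (5.40), CRISP3 in replicate 2 (7.74), CYP1A2 in replicate 1 (6.84), CFAP107 in replicate 1 (3.51) and H1-5 in replicate 4 (7.77). With MDV3100 they were PNLIPRP3 in replicate 4 (2.85), CYP4F22 in replicate 3 (3.68), KRT75 in replicate 3 (6.35), and ST6GALNAC1 (5.59) and PGC (3.98) in replicate 1. In the combination they were ASB11 in replicate 4 (3.57), GNPNAT1 in replicate 1 (9.77), MYC in replicate 4 (9.57), DAPK1 in replicate 2 (6.14) and H1-5 in replicate 4 (5.97).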

How the results depend on the processing

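Leaving out MDV3100 replicates 2 and 3, or 1 and 4, was chosen after seeing the data, from the correlations of deviations from the group mean, where centring 4 arrays alone gives -0.333. They were 0.00779 for replicates 1 and 4, -0.118 for 2 and 3, and -0.544 to -0.412 for the other pairs. The first 2 values are less negative than centring gives, and the others more negative. On the third principal component (4.36% of the variance) replicates 1 and 4 lay at 7.15 and 7.26, and replicates 2 and 3 at -6.67 and -14.5. Centring alone thus does not account for this division, and its cause was not tested. The correlation of comparisons that share no array was also added after the data were seen. The other alternatives were fixed before.

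Apart from single arrays, the gene count stayed within 1.5-fold in 56 cases and moved further in 9. For UDP-GlcNAc against PBS it was 294 without a filter and 323 with every table entry, where more genes were tested, and 842 with array weights, where the cause was not tested. It was 312 to 421 without single arrays, and the cause was not tested apart from the number of arrays. For the combination against MDV3100 it was 1178 with only the groups compared, where fewer arrays enter the variance, 1011 without MDV3100 replicates 2 and 3 and 2530 without 1 and 4. For the interaction it was 169 without a filter, 185 with every table entry, 182 to 341 without single arrays, 90 without replicates 2 and 3 and 608 without 1 and 4. As many arrays were left out in both pairs, so their number alone does not account for these counts, and the cause was not tested. With replicate number as a block, the counts were 420 for UDP-GlcNAc, 4692 for MDV3100 and 5851 for the combination against PBS, 1710 and 5246 for the combination against MDV3100 and UDP-GlcNAc, and 242 for the interaction. Counts without single arrays were 4181 to 4721 for MDV3100, 5413 to 5636 for the combination, 1405 to 1983 for the combination against MDV3100 and 4792 to 5031 against UDP-GlcNAc. No scaling moved the median of all genes by 0.1 or more.

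Among list results, apart from single arrays, 332 kept direction and side of the threshold, 49 lost the call and 5 gained it. Reversals were counted only where a call had been made, and there were 0. With an estimated correlation the call was lost for androgen-induced genes with UDP-GlcNAc (adjusted p = 0.0617) and for mitosis in each comparison: 0.392 with UDP-GlcNAc, 0.689 with MDV3100, 0.213 with the combination, 0.0760 against MDV3100, 0.237 against UDP-GlcNAc and 0.0760 in the interaction. For DNA replication it was lost at 0.237 with UDP-GlcNAc, 0.170 with the combination, 0.0668 against MDV3100, 0.237 against UDP-GlcNAc and 0.0870 in the interaction. The cause was not tested beyond the correlation assumed. With fry, which tests a list without reference to other genes, mitosis lost its call with UDP-GlcNAc (0.0545) and MDV3100 (0.157), while a call was gained for androgen-induced genes against MDV3100 (0.00240) and for the hexosamine list with MDV3100 (0.0351) and against UDP-GlcNAc (0.0183). The hexosamine list also passed with UDP-GlcNAc on ranks (0.0405) and with replicate number as a block (mean 0.0906, adjusted p = 0.0465). Its adjusted p over these alternatives ran up to 0.392, and the cause was not tested. The mitosis mean with MDV3100 lost its call at -0.174 after quantile normalization (cause not tested), and, with the cause not tested, at -0.178 without replicates 2 and 3, at -0.200 without 1 and 4, and for 3 of the means between -0.210 and -0.165 without single arrays. The correlation of UDP-GlcNAc and MDV3100 effects moved from 0.156 to 0.0559 with separate PBS arrays, by its construction, and was 0.147 to 0.194 without single arrays.

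Of 502 named gene values past the threshold, 96 lost it under at least 1 alternative and 92 under one other than leaving out a single array. Of 246 not past it, 53 passed under at least 1, and 0 reversed. Genes near the 40th percentile of an array have little signal over background, which limits what can be said of them.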

Other observations

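The 4 gene groups here were chosen after their values were seen, so all tests in this part are descriptive, and each adjusted p of a group is limma's camera adjusted over these 24 tests.

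Aryl hydrocarbon receptor targets, which include the drug-metabolizing CYP1 genes, were higher when UDP-GlcNAc was added to MDV3100: 5 of 6 rose and 0 fell, with a median log2 difference of 0.62 (adjusted p = 1.7e-05, and adjusted p = 0.062 with an estimated correlation). With MDV3100 alone CYP1A2 (2.53), CYP1A1 (0.87) and NQO1 (0.14) rose and CYP1B1 (-0.42) fell (adjusted p = 0.19). With UDP-GlcNAc alone 0 of 6 passed, with a median of 0.19 (adjusted p = 0.029, and adjusted p = 0.21 with an estimated correlation). Genes of squamous and keratinizing epithelium had a median interaction of 0.56 (adjusted p = 9.8e-05, and adjusted p = 0.013 with an estimated correlation), with 2 of 10 members past the threshold, LAMB3 (0.90) and KLK7 (1.61), of which KLK7 lost its call without MDV3100 replicates 2 and 3 (adjusted p = 0.081). Against MDV3100 4 of 10 rose, KLK7 by 1.56, LAMB3 by 1.34, SPRR1A by 1.25 and KRT80 by 0.49.

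Replication-dependent histone genes fell with the combination against PBS in 10 of 16 cases, H1-5 by 1.94 and H2AC21 by 1.34, and H2BC18 (0.90) and H2AC6 (0.19) rose, with a median of -0.34 (adjusted p = 0.0097, and adjusted p = 0.21 with an estimated correlation). Of 9 tissue kallikreins, 5 fell and 0 rose with MDV3100, with a median of -0.28 (adjusted p = 0.0050, and adjusted p = 0.062 with an estimated correlation).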
